A study of Mus musculus with 9 samples.

How the data were processed

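RNA was sequenced from 9 libraries of neural stem cells of C57BL/6 mice, per the labels. The cells came from embryos at day 14.5 with floxed alleles of Smchd1 (fl/fl), in which loxP sites flank part of the gene so that the enzyme Cre recombinase can delete it. Per the labels' protocols, every established line was divided in 2. One part received a retrovirus that carried Cre and a puromycin resistance gene, puromycin was given from 24 h after transduction, and cells were harvested on day 7; the other part stayed untransduced. The deleted cultures (del/del) therefore differ from the fl/fl cultures in retrovirus and puromycin as well as in Smchd1. RNA was isolated with a Zymo Quick RNA kit and made into libraries by standard Illumina methods, per the labels' protocols. The sample labels give 4 del/del libraries (female 1 to 3 and male 5) and 5 fl/fl libraries (female 1 to 3, male 5 and male 7). The design text of the series counts the same 4 and 5 libraries but calls them female and the controls del/fl; the sample labels were followed.

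The submitters' processing notes name bcl2fastq, TopHat2 2.0.12, edgeR 3.8.2 and the mouse genome build mm10; the read counter, the annotation release and the strand setting are not given in the sources used here. The deposited table lists 25965 genes, each with a symbol, a transcript identifier, a chromosome, a start and an end. The authors gave each gene's level in each library as log2 RPM. The values were checked against this unit: in every library at least 99.9948% of them were log2 of a whole number of reads (tolerance 0.05 reads) times 1 constant, with 0 reads entered as 0.9 reads. The constants correspond to 24.1 M to 116.6 M reads per library, of which 34.8% to 53.3% fell in listed genes, so the scaling does not equalise the share of reads in genes. A gene with no read therefore holds a different value in each library.

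The table counts reads over whole gene spans that can overlap: 7479 rows (28.8%) overlap another row, and reads in the shared stretch appear in both. The transcript identifier is shared with another row in 5879 cases, so genes were identified by symbol and place. By symbol and place, 22619 rows (87.1%) matched a gene of GENCODE release vM21. Symbols that a spreadsheet had turned into dates (25) were restored from their place.

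Groups were taken from the sample titles. Genes with a log2 level of at least 0 in at least 3 libraries were kept (14044). Tests were run on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. Del/del was compared with fl/fl over all 9 libraries with sex as a covariate (6 residual degrees of freedom). The effect in females, the effect in males, their difference, and female against male fl/fl libraries came from 1 model of 4 group means (5 residual degrees of freedom). The lone male del/del library was assumed to vary like the other groups. The recovered reads were tested with limma's voom as an alternative, and no negative binomial test was run.

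Gene lists were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over the 16 lists with at least 5 kept members, and again with a correlation estimated per list. The lists were clustered protocadherins, Hox genes, imprinted genes, X-linked genes, genes that escape X inactivation, Y-linked genes, chromatin silencing factors, germline and 2-cell genes, interferon response, p53 target, proliferation, integrated stress response, cholesterol synthesis, and RNA quality and mitochondrial genes. Markers of neural stem cells, neurons, astrocytes, the oligodendrocyte lineage, microglia and leukocytes, fibroblast and mesenchymal cells, and endothelium completed them. The comparisons, the lists, the rule for naming genes and most alternatives were fixed before the data were examined.

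The genes named are Smchd1, Xist, and in the comparisons over both sexes and in females up to 10 with the largest rise and 10 with the largest fall among genes that passed and whose del/del and fl/fl values do not overlap, without predicted genes. For each tested list the rule adds the 4 members with the smallest p in the comparison over both sexes, and for the contrasts of the sexes up to 6 per direction that passed, or the 3 with the smallest p where none did. Genes that meet this rule and are left out of the text are not reported here, while counts and list values include them. Other genes, named in the text as such, were chosen after their values were seen.

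Line numbers in the titles pair the libraries of 4 lines. As a check, each female library's deviation from its group mean was correlated across genes (genes are not independent replicates): pairs of 1 line had r of 0.868, 0.582 and 0.758, but female del/del 2 with female fl/fl 3 had 0.728 and female del/del 3 with female fl/fl 2 had 0.494. Since the growth protocol states the split, a fit with the line as a block was run as an alternative. It leaves fewer residual degrees of freedom than the main fits. Male fl/fl 7 is alone in its line, so it adds nothing to the block's estimates. The descriptions of 6 libraries begin with RNA- and those of female del/del 1, female fl/fl 1 and male fl/fl 7 do not, which was treated as a possible batch. Line 1 thus holds the only female libraries without the prefix, and pairs across the 2 naming styles had r of -0.841 to -0.572. The r of 0.868 cannot be told from the naming style, so the check does not show the pairing.

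Alternatives were no filter on low values, a stricter filter (log2 level of at least 1 in at least 4 libraries), log2 RPM plus 1, quantile normalization, centring each library on its median, limma without the trend, with robust eBayes or with array weights, the line as a block, a batch term, no sex term, female libraries alone, limma's voom weights on the recovered reads, and leaving out each library. Alternatives added after the data were seen were the 6 libraries with the prefix alone, the block or the batch term with median centring, no filter with genes without a read kept, the sex difference of lists with each library left out, and only genes with distinct sequence. The last are 7593 genes whose row overlaps no other and under 0.1 of whose 50-base transcript words, in GENCODE vM21, occur at another place. The fits were tested on simulated data of the same design with 50 genes changed per fold: over both sexes 2 were recovered at 1.5-fold, 32 at 2-fold, 46 at 4-fold and 50 at 8-fold, with 2 false calls among 13844 unchanged genes. In females 0, 17, 44 and 50 were recovered, with 3 false calls. The simulated genes were drawn independently, without line pairs or batch, so the number of false calls need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9. Reads themselves were not analysed here.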

Results

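Total RNA was sequenced from 9 libraries of neural stem cells, self-renewing cells of the developing brain that can form neurons, astrocytes and oligodendrocytes. There were 3 female del/del and 3 female fl/fl libraries from lines 1 to 3, 1 male del/del library from line 5, and 2 male fl/fl libraries from lines 5 and 7. Smchd1 encodes a chromatin protein of the SMC family that takes part in silencing the inactive X chromosome, some imprinted genes and the clustered protocadherins, and the series sets lines that lost it against their controls in both sexes. Reads in listed genes numbered 32.9 M, 39.6 M and 38.4 M in female del/del 1, 2 and 3, and 43.1 M, 12.9 M and 39.2 M in female fl/fl 1, 2 and 3. They numbered 37.9 M in male del/del 5, 36.5 M in male fl/fl 5 and 44.9 M in male fl/fl 7. M stands for 1e+06 reads. Levels are log2 RPM (reads per M reads) as the authors gave them, and 14044 genes passed the filter on low values.

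Smchd1 fell 2.28-fold in del/del cultures and did not disappear from the RNA. Its level was 5.21 ± 0.132 (SD, n = 4) in del/del and 6.39 ± 0.248 (SD, n = 5) in fl/fl libraries, which is 3047 to 3822 reads per del/del library. Over both sexes the log2 fold change was -1.19 (SE 0.148, limma adjusted p = 0.00751), and the highest del/del library, 5.36, lay below the lowest fl/fl library, 6.16. In females the log2 fold change was -1.24 (SE 0.193), which missed the threshold (limma adjusted p = 0.0921) and passed it with the line as a block (limma adjusted p = 0.0279). In the male libraries it was -1.08 (limma adjusted p = 0.830). The row covers the gene on chromosome 17, 71344489 to 71475343 (mm10, ENSMUST00000138193), introns included, so it does not tell which exons were read. The call over both sexes was lost without male del/del 5 (adjusted p = 0.0930) and in the 6 libraries with the RNA- prefix alone (log2 fold change -1.25, adjusted p = 0.0553).

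**Figure D1:**
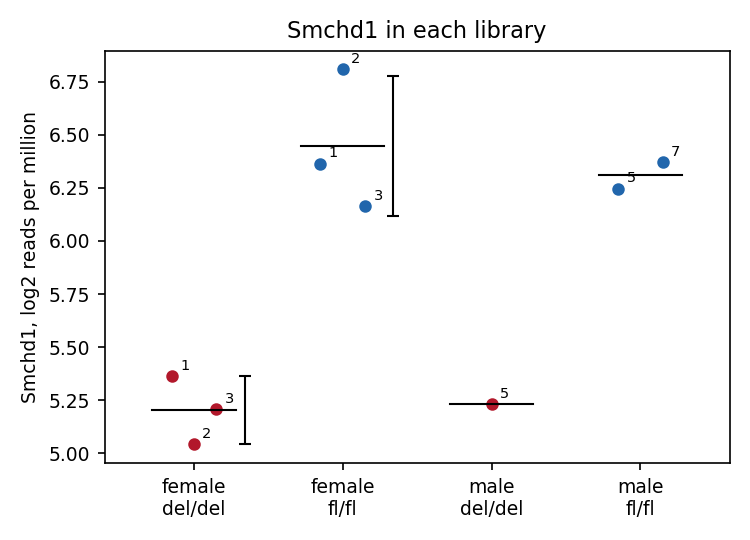
Smchd1 level (y axis, log2 RPM) in each of the 9 libraries by group (x axis); points are libraries with their line number, lines are group means, and bars, drawn for groups of 3, are SD. The 4 del/del libraries lie between 5.04 and 5.36 and the 5 fl/fl libraries between 6.16 and 6.81.

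Over both sexes (4 del/del against 5 fl/fl libraries) 203 genes rose and 14 fell after deletion by limma, so that 93.5% of the changes were rises. The largest rise was that of Slitrk4, a neuronal transmembrane protein gene on the X chromosome (64264885 to 64276996), which rose 21.7-fold (log2 fold change 4.44, SE 0.625, adjusted p = 0.00957). It started from 2 to 27 reads per fl/fl library and reached 134 to 225 reads in del/del, so its fold rests on few control reads. With log2 RPM plus 1, which shrinks changes of low genes, its log2 fold change was 1.38. Ajap1, a gene for a protein of adherens junctions, rose 10.9-fold (log2 fold change 3.45, SE 0.600), Dcaf12l1 on the X chromosome 10.7-fold (3.42, SE 0.451), and Tacr1, the receptor of substance P, 9.61-fold (3.26, SE 0.495). Also among the 10 largest rises were Gbp9, Gbp8, Trim34b, Pyhin1 and Usp18, which are known as interferon-induced genes or members of such families, and Pcdhb4 of the protocadherin cluster, with log2 fold changes of 2.70 to 2.87. With log2 RPM plus 1 the 10 kept their calls at smaller sizes, such as 2.48 for Ajap1, 1.17 for Dcaf12l1, 1.16 for Tacr1, 1.00 for Trim34b, 1.30 for Pyhin1, 1.47 for Usp18 and 1.38 for Pcdhb4. Gbp8 (chromosome 5, 105014153 to 105139540) and Gbp9 (105078394 to 105139539) overlap and share reads, and 56.8% of the transcript words of Trim34b occur at another place. Falls were smaller: the largest were those of Hmcn1, an extracellular matrix gene (log2 fold change -1.47, SE 0.204, a 2.76-fold fall), Smchd1, and the X-linked Prrg3 (-0.99, SE 0.138), leaving aside the predicted gene Gm20631 (-1.41), whose row overlaps Hmcn1.

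Other large falls belonged to Insm1, a transcription factor of neuroendocrine and neuronal progenitors, Hhip, an inhibitor of hedgehog signalling, Sstr4, a somatostatin receptor, Csrnp3, Lmo3 and Syt6, with log2 fold changes from -0.89 to -0.59. With the line as a block 529 genes rose and 32 fell, and 214 of the 217 also passed there, while the block with median centring gave 226 rises and 24 falls. In the 6 libraries with the RNA- prefix 174 rose and 6 fell, and of these 180 genes 171 had the same sign in the female line 1 pair, the only pair without the prefix, against 43.5% of all kept genes. The median level of all kept genes was also higher in female del/del 1 (4.385) than in female fl/fl 1 (4.202). Most of the 180 were rises, so 43.5% is not the share to expect for them, and part of the sharing may be this shift. The number called depended on the libraries used. Male del/del 5 is the only male del/del library, so without it the effect comes from the females alone. There only Gbp8 and Gbp9 rose and 0 genes fell. With the line as a block the females gave 262 rises and 13 falls (23 and 1 with median centring added). A call lost without male del/del 5 is thus one that the females alone did not reach without the block. Without female del/del 2, female del/del 1 or female fl/fl 3 the counts were 50, 61 and 88 rises with 4, 5 and 6 falls. Without male fl/fl 5 there were 112 rises and 5 falls, without male fl/fl 7 there were 243 and 9, and without female del/del 3 135 genes passed (93.3% rises).

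The 10 rises and 9 falls named here kept their sign whichever library was left out, but not always their call. Of these 19, 8 passed without female del/del 2, 11 without female del/del 1, 13 without female del/del 3 or female fl/fl 3, and 14 without male fl/fl 5. Without male fl/fl 7, female fl/fl 1 or female fl/fl 2 the numbers were 17, 18 and 18, and without male del/del 5 the number was 2. With quantile normalization 11 of the 19 passed, Slitrk4 not among them (adjusted p = 0.0625), and 86 genes rose and 18 fell in all, or 82.7% rises. The 2 that passed in each of these settings were Gbp8 and Gbp9.

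Interferon response genes rose together after deletion. Of the 24 kept members of the list, 12 rose and 0 fell over all genes tested (20 rose adjusted over the list alone), with a median log2 fold change of 0.92, or 1.90-fold (limma camera adjusted p = 1.19e-25, and adjusted p = 0.0495 with an estimated correlation). Usp18, which removes ISG15 from proteins and dampens interferon signalling, rose 6.60-fold (log2 fold change 2.72, SE 0.387), and Oasl2, of the oligoadenylate synthetase family, 5.61-fold (2.49, SE 0.335). Lgals3bp, a secreted galectin-binding glycoprotein, rose 4.17-fold (2.06, SE 0.240), the antiviral gene Rsad2 3.37-fold (1.75, SE 0.218), and Ifih1, a sensor of double-stranded RNA, 2.59-fold (1.37, SE 0.174). The median level of the list was 2.42 to 2.73 in the 4 del/del libraries and 0.78 to 1.35 in the 5 fl/fl libraries. Members that did not pass, chosen after their values were seen, included Isg15 at 2.10 (adjusted p = 0.0641), Stat2 at -0.14 and Gbp3 at -0.04. With the line as a block 16 of the 24 rose, Isg15 among them (adjusted p = 0.0188). None of the 24 passed without male del/del 5, where the list median was 0.88, and 5 passed with quantile normalization. Since the deleted cultures alone received retrovirus and puromycin, this comparison cannot separate these from the loss of Smchd1.

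Clustered protocadherins, neuronal adhesion genes arranged in 3 arrays on chromosome 18, rose as a list made up mostly of the beta array. Of 19 kept members 17 were beta genes, and the others were Pcdhac1 of the alpha array and Pcdhga11 of the gamma array. The list thus says little of the gamma array. Of the 19, 7 rose (11 adjusted over the list alone) and 0 fell, with a median log2 fold change of 0.89, or 1.85-fold (limma camera adjusted p = 2.29e-18, but adjusted p = 0.0600 with an estimated correlation). All 19 estimates were above 0 as deposited, with quantile normalization and with median centring, 18 were with voom, and 17 were in the 6 libraries with the RNA- prefix. Pcdhb4 rose 6.49-fold (log2 fold change 2.70, SE 0.518), Pcdhb2 3.24-fold (1.70, SE 0.265), Pcdhb11 3.00-fold (1.59, SE 0.207) and Pcdhb5 2.31-fold (1.21, SE 0.152). The row of Pcdhac1, which spans the alpha array from 36930285 to 37187657, rose 2.41-fold (1.27, SE 0.170). Pcdhb3 and Pcdhb7 were the other members that rose, while Pcdhb19 had 0.12 and Pcdhga11 0.03 (members chosen after their values were seen). Del/del and fl/fl values did not overlap in 9 of the 17 beta genes, where chance gives 1.59% and all kept genes gave 6.52%. None of the 19 passed without male del/del 5, and Pcdhb2 also failed without female del/del 1 or 2 (adjusted p = 0.0585 and 0.0718). Pcdhb4 failed without any 1 library except female fl/fl 1 or 2 (adjusted p up to 0.155), and 3 of the 19 passed with quantile normalization.

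**Figure D2:**
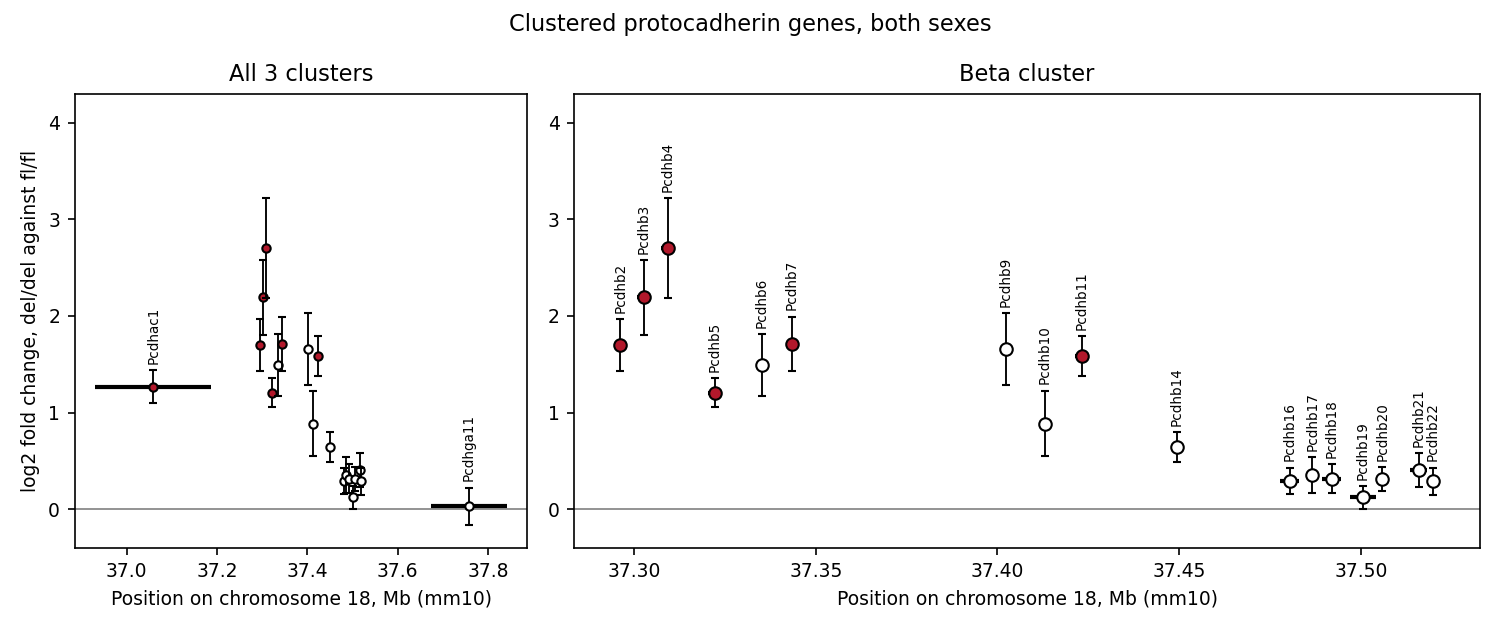
Log2 fold change of del/del against fl/fl (y axis, error bars SE, n = 4 and 5) by position on chromosome 18 (x axis, Mb) for the 19 clustered protocadherins that passed the filter, over the whole locus and over the beta array. Horizontal bars are the rows' spans, and filled points are the 7 genes that rose, among them Pcdhb4 at 2.70.

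**Figure D3:**
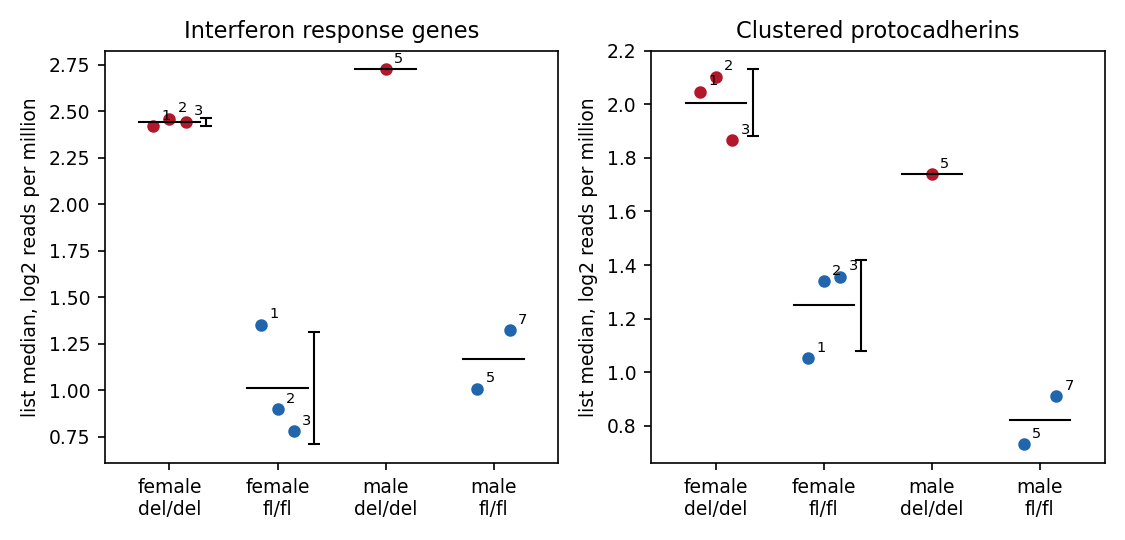
Median level (y axis, log2 RPM) of the interferon response genes and of the clustered protocadherins in each library by group (x axis); points carry the line number, lines are group means, and bars, drawn for groups of 3, are SD. The interferon median lies between 2.42 and 2.73 in del/del and between 0.78 and 1.35 in fl/fl libraries.

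Among imprinted genes, the neighbours Dlk1 and Meg3 on chromosome 12 and the Polycomb-related Sfmbt2 on chromosome 2 rose. Dlk1, an inhibitory Notch ligand, rose 5.00-fold (log2 fold change 2.32, SE 0.323, limma adjusted p = 0.00923), and the maternally expressed noncoding RNA Meg3 rose 4.68-fold (2.23, SE 0.278, limma adjusted p = 0.00751). Sfmbt2 rose 5.66-fold (2.50, SE 0.438, limma adjusted p = 0.0232) from 5 to 34 reads per fl/fl library, and had 0.825 with log2 RPM plus 1. These 3 were the only members that passed of 41 (6 rises and 1 fall adjusted over the list alone), and Kcnq1 had 0.40 (adjusted p = 0.0662). None passed without male del/del 5 (Meg3 and Dlk1 adjusted p = 0.0930), and Sfmbt2 passed only without female fl/fl 1, female fl/fl 2 or male fl/fl 7 (adjusted p up to 0.286 otherwise). The list had a median of 0.04 and a mean of 0.23 and did not pass (adjusted p = 0.0867), but passed without female fl/fl 2 (adjusted p = 0.0407), without a filter on low values (0.0214, and 0.00311 with readless genes kept) and with array weights (0.0478).

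No shift of the X chromosome as a whole passed the test as deposited. X-linked genes had a median log2 fold change of -0.04 against -0.00 for other genes (484 genes, limma camera adjusted p = 0.143, and 0.0442, pointing down, with the block and median centring), with a mean of 0.03 of the opposite sign. In females, which alone carry an inactive X, the median was -0.05, the mean 0.01 and the test pointed down (adjusted p = 0.0799, 0.0214 without female fl/fl 1, 0.901 without female fl/fl 2, 0.0479 with quantile normalization, and 0.0452 with readless genes kept), and in males -0.01 (adjusted p = 0.678). Without female fl/fl 2 the median over both sexes turned to 0.09, with 338 of 484 genes above 0. The medians of all other tested lists but interferon response genes moved up there too, so this move is not particular to the X chromosome. Of the X-linked genes 8 rose (1.65%) and 2 fell, the same counts adjusted over the list alone, against 195 rises among 13560 other genes (1.44%, Fisher's exact test across genes, two-sided, p = 0.696). Besides Slitrk4 and Dcaf12l1, Ptchd1, a gene tied to intellectual disability, rose 2.32-fold (log2 fold change 1.21, SE 0.195, limma adjusted p = 0.0177). That call was lost without male del/del 5, female del/del 1, female del/del 2 or female fl/fl 3 (adjusted p 0.0592 to 0.168). Xist, the RNA that coats the inactive X, differed by 0.07 in females (SE 0.276, limma adjusted p = 0.999), with levels of 7.79 to 8.75 in the 6 female libraries and -2.47 to -1.46 in the 3 male libraries. In lines 1 and 3 Xist was higher in del/del (8.43 against 7.81, and 8.09 against 7.79). In line 2 Xist was lower in del/del (8.06 against 8.75 in female fl/fl 2). In each female line Xist thus moved the same way as the median of all kept genes. Over both sexes it had 0.27, -0.79 with quantile normalization and 1.78 without a sex term (adjusted p = 0.992 as deposited), and it passed with array weights alone (0.51, adjusted p = 0.0264; range over alternatives 0.0264 to 1). Its reads are nearly the same as those of the overlapping Tsix row (141341 and 141387 in all), so the strand is unknown. Genes that escape X inactivation had a median of -0.01 and a mean of 0.03 with 0 of 13 passing by limma, also adjusted over the list alone (list adjusted p = 0.724), among them Car5b at 0.43 and Kdm6a at 0.11.

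Of 12 astrocyte markers 3 rose in del/del, and the list passed with a fixed correlation (limma camera adjusted p = 3.50e-05) but not with an estimated correlation (adjusted p = 0.278). Gfap, the intermediate filament of astrocytes, rose 4.19-fold (log2 fold change 2.07, SE 0.346), the water channel gene Aqp4 3.17-fold (1.66, SE 0.291), and the glutamate transporter gene Slc1a2 1.58-fold (0.66, SE 0.123). The gap junction gene Gja1 had 0.40 (adjusted p = 0.207, and 0.0272 without female fl/fl 2). The list had a median of 0.34, with 4 rises adjusted over the list alone. The calls of Gfap, Aqp4 and Slc1a2 were lost without male del/del 5, female del/del 1, female del/del 2 or female fl/fl 3, those of Aqp4 and Slc1a2 also without female del/del 3, and that of Slc1a2 without male fl/fl 5 (adjusted p 0.0538 to 0.257).

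Among neuron markers the neurofilament genes Nefm and Nefl rose, 2.82-fold (log2 fold change 1.49, SE 0.147) and 2.38-fold (1.25, SE 0.159), and their rows overlap, so that part of the reads are counted for both. Both calls were lost without male del/del 5 (adjusted p = 0.0717 and 0.0930), and that of Nefl in the 6 libraries with the prefix (0.0577). Gad1, which makes the transmitter GABA, had 0.80 (limma adjusted p = 0.214, 0.0348 with the line as a block, and 0.0461 without female fl/fl 1). Tubb3 had -0.36 (adjusted p = 0.514). As a list the neuron markers did not pass, with 2 of 12 rising (3 adjusted over the list alone), a median of -0.08, a mean of 0.17, and a test that pointed up (adjusted p = 0.337, and 0.0140 with readless genes kept). Neural stem cell markers had a median of -0.06 with 0 of 23 passing by limma over all genes or over the list alone (list adjusted p = 0.263). Without female fl/fl 2 their median was 0.11, with 20 of 23 above 0, but nearly all tested lists moved up there. With all libraries Notch1 had 0.24, Msi1 0.17, Olig2 -0.23 and Nr2e1 0.12. Oligodendrocyte lineage markers had -0.09, and 0.04 without female fl/fl 2, with 0 of 9 passing in either way (adjusted p = 0.229); Bcas1 had -0.26, Cnp -0.09 and Olig1 -0.09.

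Of the markers of cells that the cultures should lack, none passed over all genes, but with the line as a block the endothelial marker Flt1 did (log2 fold change 1.84 and adjusted p = 0.106 without the block, 0.00995 with it; chosen after its values were seen). Fibroblast and mesenchymal markers had a median of 0.23 with 0 of 6 passing (2 rises adjusted over the list alone, list adjusted p = 0.101), among them the collagen gene Col6a1 at 1.39 (limma adjusted p = 0.105, and 0.0403 without female del/del 3), Fn1 at 0.58, Acta2 at 0.28 and Tagln at 0.18. The list passed over both sexes in 4 of 26 alternatives: without a filter on low values (median 0.55, adjusted p = 0.00515), with readless genes kept too (0.52, 0.00228), without male fl/fl 7 (0.0369), and with the block and median centring (0.0386). In females it had a median of 0.27 (adjusted p = 0.0539) and passed in 9 of 26, without a filter at 0.000803. Of the microglia and leukocyte markers 4 of 13 passed the filter on low values (median -0.03, 1 rise adjusted over the list alone), and of the endothelial markers 4 of 10 (median 0.34, 1 rise adjusted over the list alone); these lists were too short for a list test.

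Lists of growth and metabolism had medians below 0 in del/del over both sexes, which moved near or above 0 without the shallow library female fl/fl 2. Cholesterol synthesis genes had a median log2 fold change of -0.18 with 21 of 21 estimates below 0 (limma camera adjusted p = 0.000377), proliferation genes -0.15 with 30 of 32 (0.000266), integrated stress response genes -0.15 with 17 of 20 (0.0164) and chromatin silencing factors -0.09 with 33 of 45 (0.0105). With an estimated correlation each had an adjusted p = 0.725. Without female fl/fl 2 the medians were -0.01, 0.00, 0.05 and 0.05, the last 3 of the opposite sign, and the limma camera adjusted p were 0.0821, 0.0407, 0.610 and 0.162. Nearly all tested lists moved up there, and camera sets a list against the other genes. The proliferation list thus still passed, pointing down, with a median near 0. The stress response list also failed without female del/del 3 (0.0822). The male effect does not use female fl/fl 2 but rests on 1 del/del library. Its medians were -0.09 for cholesterol (19 of 21 below 0) and -0.12 for proliferation (30 of 32). They were 0.03 for the stress response (7 of 20) and -0.05 for silencing factors (30 of 45). Over both sexes 0 single members of the first 3 lists passed by limma, also adjusted over the list alone, and Smchd1 was the only one of the silencing factors. Examples were Lss at -0.29, Mvd at -0.23, Dhcr7 at -0.23 and Pmvk at -0.20 for cholesterol, Tyms at -0.28, Bub1 at -0.26, Cdc6 at -0.17 and Aurka at -0.17 for proliferation, Trib3 at -0.38, Slc7a11 at -0.30, Shmt2 at -0.23 and Cebpb at 0.26 for the stress response, and Cbx2 at -0.25, Kdm2b at -0.22 and Ezh1 at 0.19 for silencing.

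Of the p53 targets Perp, a desmosomal gene, rose 2.27-fold (log2 fold change 1.18, SE 0.158), 1 of 25 members also adjusted over the list alone, and the call was lost without male del/del 5 (adjusted p = 0.0930). Fas had 0.60, Dcxr 0.33 and Tnfrsf10b 0.31, and the list had a median of 0.02 (adjusted p = 0.273, 0.00887 without female fl/fl 2, 0.00754 with quantile normalization and 0.0377 with array weights; range over alternatives 0.00754 to 0.796). Of the RNA quality and mitochondrial genes the nuclear noncoding RNA Neat1 rose 1.62-fold (0.70, SE 0.143, limma adjusted p = 0.0474), 1 of 10 members also adjusted over the list alone. That call was lost without any 1 library other than female del/del 3 (adjusted p 0.0545 to 0.365). Hspa1b had 0.47, Hspa1a 0.44 and Fos 0.13, and the list had a median of 0.09 (adjusted p = 0.229, 0.00577 without female fl/fl 2, 0.0292 with quantile normalization and 0.00585 with array weights; range over alternatives 0.00577 to 0.885). Hox genes, which mark position along the body axis, had 5 to 76 reads over 39 genes per library, and 0 passed the filter on low values. Germline and 2-cell genes had 2 of 24 kept members, with a median of 0.55 and 1 rise adjusted over the list alone.

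In females (3 against 3 libraries) the interferon-inducible GTPase genes Gbp8 and Gbp9 rose, 6.74-fold (log2 fold change 2.75, SE 0.251, limma adjusted p = 0.0228) and 7.03-fold (2.81, SE 0.283, limma adjusted p = 0.0259). No other gene passed by limma (2 rises and 0 falls, 916 genes at an unadjusted p under 0.05, and by voom 2 rises and 1 fall, with Gbp8 and Gbp9 not among them at adjusted p = 0.0832 and 0.0836). With the line as a block 262 genes rose and 13 fell, and with a batch term 44 rose, but with median centring added these were 23 and 1 for the block and 3 and 1 for the batch term. The 200 genes with the smallest p were higher in del/del in 193 cases. As lists, interferon response genes had a median of 0.88 (15 of 24 rises adjusted over the list alone, camera adjusted p = 2.33e-21, but adjusted p = 0.0716 with an estimated correlation). Protocadherins had 0.69 (10 of 19 adjusted over the list alone, 5.07e-17, but adjusted p = 0.121 with an estimated correlation), and astrocyte markers 0.27 (3 of 12, 0.000222, but adjusted p = 0.459 with an estimated correlation). Proliferation, stress response, cholesterol and silencing lists had medians below 0 (adjusted p from 0.000222 to 0.00729, each adjusted p = 0.786 with an estimated correlation). Without female fl/fl 2 their medians turned to 0.09, 0.06, 0.07 and 0.11 and none passed (adjusted p 0.139 to 0.397). With female del/del 1, 2 or 3 left out, 0 genes rose and 0 fell. Leaving out male fl/fl 7 gave 1 rise (neither Gbp8, adjusted p = 0.0542, nor Gbp9, 0.0690), male fl/fl 5 gave 3 rises without Gbp9 (0.0530), female fl/fl 1 gave 5, and female fl/fl 2 gave 6 rises and 1 fall.

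In males (1 against 2 libraries) 0 genes passed in either direction by limma (370 at an unadjusted p under 0.05), and 0 by voom (629). With the line as a block, in which the male effect is 1 library against 1 of line 5, 47 rose and 2 fell, and with the block and median centring 0 did. Every male value rests on 1 del/del library, which the tests assume to vary like the other groups. All 200 genes with the smallest p in females had the same sign in males, against 64.0% of all kept genes. Gbp8 had a log2 fold change of 2.95, Usp18 3.30, Meg3 2.24 and Slitrk4 4.05 in males. The median was 1.16 for interferon response genes, with 17 of 24 rises adjusted over the list alone (camera adjusted p = 5.43e-37, and adjusted p = 0.0208 with an estimated correlation). It was 1.17 for protocadherins, with 5 of 19 (1.04e-17, but adjusted p = 0.111 with an estimated correlation), and 0.40 for astrocyte markers, with 2 of 12 (3.70e-06, but adjusted p = 0.245 with an estimated correlation). Imprinted genes had 0.04 (0.0449, but adjusted p = 0.843 with an estimated correlation), RNA quality genes 0.36 (0.00387, but adjusted p = 0.676) and proliferation genes -0.12 (0.00541, but adjusted p = 0.843).

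The effect of deletion was not shown to differ between the sexes in any gene: 0 passed in either direction by limma, with 6 at an unadjusted p under 0.05, and 0 by voom (18 at an unadjusted p under 0.05). Chance alone would put a share of about 0.05 of the 14044 genes under that unadjusted p. Far fewer lay there, so the test was strict here and its lack of calls does not show equal effects. The smallest p in each direction belonged to Rai2, Itga2 and Gm11944, with differences (female minus male effect) of 0.84, 0.61 and 0.72, and to Scg2, Lgals3 and Irs4, with -0.79, -0.77 and -0.61. For Smchd1 itself the effect was -1.24 in females and -1.08 in males. As lists, the test of the difference passed for interferon response genes (median 0.88 in females and 1.16 in males, camera adjusted p = 7.46e-06, but adjusted p = 0.920 with an estimated correlation). It sets the females against 1 male del/del library, which had the highest interferon median of the 4 del/del libraries, so it does not tell sex from that library. Without female fl/fl 1 this test failed (adjusted p = 0.220). The test also passed, with the same limit, for integrated stress response genes (-0.24 and 0.03, 9.53e-07, but adjusted p = 0.927 with an estimated correlation) and for RNA quality genes (0.01 and 0.36, 0.000660, but adjusted p = 0.927 with an estimated correlation). The gap between these medians rested on female fl/fl 2: without it the female medians were 0.06 and 0.36 beside 0.03 and 0.36 in males. Set against the other genes, as the test does, both lists still had the lower effect in females there, and both still passed.

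Female and male fl/fl libraries (3 against 2) differed in 2 genes that were higher in females, Xist and the overlapping Tsix (log2 difference 10.3, SE 0.309, limma adjusted p = 6.58e-07), and in 3 that were lower, the Y-linked Kdm5d, Eif2s3y and Uty. The female fl/fl libraries held 0 to 2 reads of Kdm5d, 0 to 3 of Eif2s3y and 0 to 5 of Uty, and the male libraries 3553 to 4468 reads of these genes, so the fitted differences depend on the value entered for 0 reads and are not given as folds. Y-linked genes had 4 of 8 members kept, and none differed by deletion over both sexes or adjusted over the list alone. No library had sex genes at odds with its label. The median of all genes differed by 0.09 between the sexes as deposited and by -0.01 with quantile normalization. The falls were not called without male fl/fl 5 or male fl/fl 7 (0 genes), and 1 was without male del/del 5, where Kdm5d had adjusted p = 0.0828 and Uty 0.0709.

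The libraries also differed in a way the groups do not explain. Female del/del 1, female fl/fl 1 and male fl/fl 7, whose descriptions lack the RNA- prefix, lay at -63.45, -68.18 and -63.36 on the first principal component (67.8% of the variance), and the other 6 libraries between 29.04 and 45.86. Among the latter, the second component (14.7%) set female fl/fl 2, the shallowest library, at 51.80. It held 24.1 M reads by its scaling constant against 74.0 M to 116.6 M in the others, and 53.3% of them lay in listed genes against 34.8% to 44.4%. Each naming style held both genotypes, and with a batch term 381 genes rose and 17 fell, all 217 of the original calls included.

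**Figure D4:**
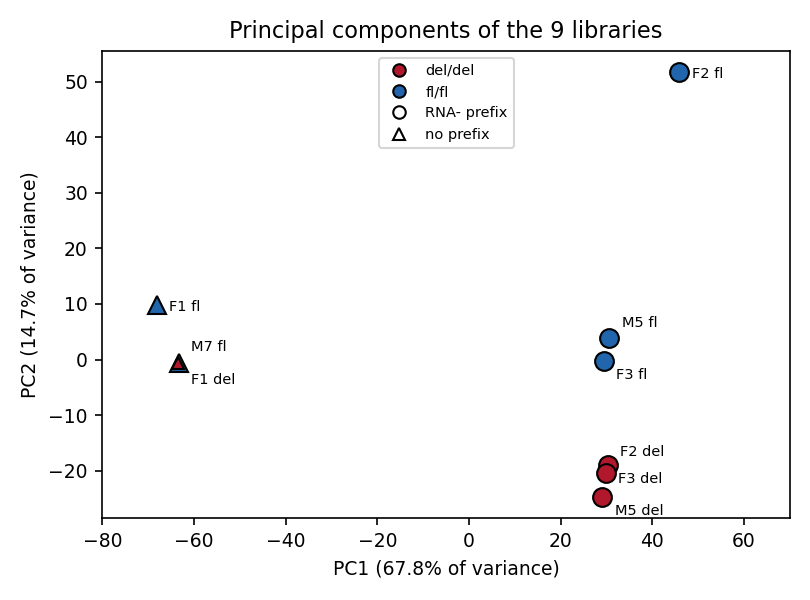
First and second principal component (axes, in component units with their share of variance) of the 9 libraries, by genotype (colour) and by the naming style of the description (shape). The 3 libraries without the prefix lie at -68.18 to -63.36 on the first component and the other 6 at 29.04 to 45.86.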

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

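Of the tests in this part, those of sequencing depth and of other splits of the libraries were set out before their results were seen, and those of leukocytes, library batch, transduction, scaling, the shallow library, genes near the floor, reads with several places and line of origin were chosen after. A library was singled out when its gap to the nearest other library of its genotype was large against the range of the group. This was so for 24 of 212 values (11.3%), where chance gives about 1 in 20 for independent values. These values come from the same libraries, and list medians share genes with single members, so the share does not test for an excess.

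Among the 4 del/del libraries, female del/del 1 stood apart in 7 values. It had 19201 genes with reads (20378 to 20452 in the others), a median log2 level of 4.385 (4.196 to 4.225), and a first principal component of -63.45 (29.04 to 30.25). The median of its p53 target genes was 5.6254 (5.1245 to 5.2004). Among single genes it was highest in Notch1 (7.0996 against 6.4784 to 6.5262), Olig1 (6.1597 against 5.6203 to 5.6641) and the mitotic checkpoint gene Bub1 (5.7624 against 5.4002 to 5.4332). Male del/del 5 had the highest median of interferon response genes, 2.725 (2.4213 to 2.4611). Female del/del 3 was highest in Prrg3, 3.8103 (3.2766 to 3.3673), and in Pmvk of cholesterol synthesis, 5.3869 (5.0223 to 5.0530).

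Among the 5 fl/fl libraries all 14 such values belonged to female fl/fl 2. It had 24.12 M reads by its scaling constant (104.9 M to 116.6 M in the others), 53.3% of them in listed genes (34.83% to 38.92%), and a second principal component of 51.8 (-0.7023 to 9.869). Its medians were high for imprinted genes (5.1927 against 4.2775 to 4.4543), X-linked genes (4.5464 against 4.0765 to 4.1841) and neural stem cell markers (5.8848 against 4.7263 to 4.9336). They were also high for integrated stress response genes (6.6791 against 5.4437 to 5.6041) and cholesterol synthesis genes (6.8296 against 5.8252 to 6.1129). Olig2 (6.6929 against 5.5907 to 5.7008), Olig1 (6.7766 against 5.4182 to 5.7161), Tyms (4.7983 against 4.0810 to 4.2360), Shmt2 (6.8484 against 5.9757 to 6.1527) and Dhcr7 (6.6483 against 5.8252 to 5.9895) were highest in it. Pcdhb4 was lowest in it, at -3.0069 (-0.76321 to -0.43973), from 3 reads.

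For 3 lists a test of the difference between the female and the male effect of deletion passed with an inter-gene correlation fixed beforehand. These were interferon response genes (adjusted p = 7.46e-06, median 0.88 in females and 1.16 in males), integrated stress response genes (9.53e-07, -0.24 and 0.03) and RNA quality and mitochondrial genes (0.000660, 0.01 and 0.36). With an estimated correlation the adjusted p were 0.920, 0.927 and 0.927, and the male effect rests on 1 del/del library, which itself stood apart in interferon response genes, so a difference between the sexes is not shown. Without female fl/fl 2 the female medians of the last 2 lists were 0.06 and 0.36, close to the male ones, so the gap between the medians rests on that library. Set against the other genes, as the test does, both lists still had the lower effect in females there, and both still passed. Without female fl/fl 1 the interferon list failed (0.220). Other lists passed with 1 library left out, not always in 1 direction. Cholesterol synthesis passed without female del/del 3 or female fl/fl 1, with the lower effect in females. Without female fl/fl 2 it passed with the higher effect in females (median 0.075, against -0.0917 in males). Proliferation passed without female fl/fl 2, and astrocyte markers without female fl/fl 2 or male fl/fl 7. So did p53 targets without male fl/fl 7 and X-linked genes without male fl/fl 5.

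The first pattern weighed is the rise of interferon response genes. Leukocytes or microglia in the del/del cultures are argued against as the cells that held the added reads. The 9 of their genes with low control level rose by a summed 0.191 RPM, which is 0.324% of the 58.9 RPM by which the interferon genes rose. Whether a few such cells raised these genes in the other cells was not tested. The library batch is argued against as the whole cause, since in the 6 libraries with the RNA- prefix the list had a median log2 fold change of 1.04 (limma camera adjusted p = 2.54e-22). In the female line 1 pair, which lacks the prefix, it had a median of 0.633 with 23 of 24 genes higher. The median level of all kept genes was also higher in female del/del 1 (4.385) than in female fl/fl 1 (4.202), so part of this count may be that shift. Retroviral transduction and puromycin cannot be told apart from the loss of Smchd1, because 0 libraries received one without the other. Both may therefore contribute.

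The next pattern is that rises outnumbered falls, with 93.5% of the 217 changes. The authors' scaling is argued against as the whole cause: it would move all genes by about the size of the rises, but the library medians differed by 0.0151 log2 units between del/del and fl/fl (SE 0.0826, upper 95% limit 0.217), and the lowest of the 203 rises was 0.494. Without the shallow library female fl/fl 2 the share was 93.4%, and among genes in the upper 80% of levels it was 87.5% (91 rises and 13 falls), which argues against that library and against genes near the floor as the whole cause. The upper 80% held only 91 of the 203 rises but 13 of the 14 falls. Genes of the lowest levels thus supplied most rises and may add to the excess. A loss of repression after deletion may explain the excess, a hypothesis that these libraries cannot part from an effect of transduction.

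The last is that 3 libraries stood apart on the first principal component. Sequencing depth is argued against: with all libraries thinned to 12.85 M reads in genes, the component held 62.1% of the variance and still parted them. Reads that match several places may have been counted in 1 batch and not in the other. Genes with at least 50% of their transcript words at another place differed 18.5 times as much between the naming styles as genes with distinct sequence (315 genes, median absolute log2 difference 1.42, against 7593 genes, 0.0768), and 174 genes were at least 4 log2 units lower without the prefix, while 0 were higher. The line of origin cannot be told apart from the batch, because 0 lines have libraries of both styles.

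Other splits of the 9 libraries into 4 and 5 (100 drawn of all possible) were set beside the real one. For the number of genes called, 3 splits gave as many, the real one included. The libraries are not interchangeable, given their lines, their naming styles and female fl/fl 2. A share over splits that ignore this cannot exclude chance, and the highest other, 4225 genes, is far above the real 217. That split set the 3 male libraries and female fl/fl 2 against the other females, so with sex in the model it rests on female fl/fl 2 alone, and the other (4203 genes) rests on female fl/fl 2 and female del/del 1. Both point to a structure of the samples set by these libraries rather than by genotype. The 13 splits drawn that part all 4 pairs of a line, as the real one does, are too few for a share under 0.05; the highest other among them was 0 genes. Splits with a median as large, the real one included, were 2 for clustered protocadherins (real 0.885, highest other 1.1) and 2 for interferon response genes (0.923, 0.988). For astrocyte markers (0.338, 0.374) they were 3. For the first 2 lists the other split set 4 fl/fl libraries against the rest, so it is close to the real grouping. These shares do not exclude chance either. Among the 13, again too few, the highest other medians were 0.577, 0.679 and 0.374, the last above the real one. Over all splits drawn chance is not excluded for chromatin silencing factors (real -0.0931, highest other 0.471, 67 splits as large), proliferation genes (-0.147, 0.642, 58), integrated stress response genes (-0.153, 0.725, 69) or cholesterol synthesis genes (-0.185, 0.786, 55). In females 10 splits are too few for a share under 0.05; the real split called 2 genes, the highest other 0, and 1 split as many.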

How the results depend on the processing

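The sex difference of lists with 1 library left out and the settings with the RNA- prefix alone, with distinct sequence, with readless genes kept, and with centring joined to the block or batch term were chosen after the data were seen. Of the log2 fold changes of named genes, 1384 values kept direction and side of the threshold in settings that kept all libraries or a named set, 53 fell short of it, 23 newly passed and 3 changed sign. With 1 library left out the numbers were 677, 122, 3 and 2. List tests gave 547 unchanged, 16 lost and 26 gained, and with 1 library left out 277, 8 and 11. Counts of changed genes stayed within 1.5 times in 121 cases, were lower in 6 and higher in 33, and with 1 library left out in 63, 20 and 3. Smchd1 was lower in all 26 alternatives over both sexes (log2 fold change -1.27 to -1.07, adjusted p 3.09e-05 to 0.0930, 24 passing). Unless stated, the cause of a change was not tested.

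Without a filter on low values the imprinted list passed (adjusted p = 0.0214), and with readless genes kept too (0.00311), as did the fibroblast list (0.00515 and 0.00228, range 0.00228 to 0.725) and, in females, the imprinted (0.0223 and 0.00237), neuron (0.0252 and 0.00458) and fibroblast lists (0.000803 and 0.000357). With readless genes kept, the neuron list passed over both sexes (0.0140) and the X-linked list in females (0.0452), and 59 genes rose and 1 fell in females. Over all alternatives the imprinted list ranged from 0.00311 to 0.725. A stricter filter left 0 falls between the sexes. With log2(CPM + 1) 38 genes rose and 1 fell in females, and the fibroblast list passed there (0.0484), as with female libraries alone (0.0359). With quantile normalization 86 rose over both sexes, 1 fell in females, the p53 (0.00754, in females 0.0214) and RNA quality (0.0292) lists passed, X-linked (0.0479) and fibroblast (0.0353) lists passed in females, and Xist over both sexes reversed to -0.786. With median centring 0 rose and 1 fell in females. Without an intensity trend 53 rose in females and 1 in males, and with robust eBayes 77 rose and 4 fell in females.

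Array weights, which let single libraries count less, gave 1122 rises and 252 falls over both sexes, 1837 and 426 in females and 11 rises in males. With them the imprinted (0.0478), p53 (0.0377) and RNA quality lists (0.00585, in females 0.00558) passed, the stress response list (0.290) and in females the silencing (0.0783) and cholesterol lists (0.185) failed, Xist passed (log2 fold change 0.51, adjusted p = 0.0264), and the log2 fold changes of Cnp (0.0204) and Olig1 (0.0786) changed sign without passing. The line as a block gave 529 rises and 32 falls over both sexes, 262 and 13 in females and 47 and 2 in males. Among genes named by the rule it also let Gad1 pass over both sexes and Smchd1 in females, and it changed no list call. The batch term gave 381 rises over both sexes and 44 in females. By voom 28 fell over both sexes and 1 in females. With an estimated inter-gene correlation the lists of protocadherins (0.0600), astrocyte markers (0.278), chromatin silencing, proliferation, stress response and cholesterol (each 0.725) failed, and in females these 6 (0.121 to 0.786) and the interferon list (0.0716).

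Among genes with distinct sequence, fewer of which are tested, 74 rose and 4 fell in females, and 0 were higher in female than male controls because the Xist and Tsix rows overlap and are left out. In the 6 libraries with the prefix, fewer samples, 6 fell over both sexes, 0 rose in females, and 5 were lower in female than male controls. The block with centring gave 226 rises and 24 falls over both sexes, 23 rises and 1 fall in females, 0 in males, and X-linked (0.0442) and fibroblast lists (0.0386, in females 0.0294) that passed. The batch term with centring gave 23 falls over both sexes and 1 in females.

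With 1 library left out, rises over both sexes ranged from 2 to 243 and falls from 0 to 15, rises in females from 0 to 6 and falls from 0 to 1, and falls between the sexes from 0 to 4. The adjusted p ranged from 0.0407 to 0.146 for imprinted genes, 0.00493 to 0.162 for silencing factors, 0.000220 to 0.610 for the stress response and 4.58e-05 to 0.0821 for cholesterol over both sexes, and from 0.0214 to 0.901 for X-linked genes in females. The lowest count of rises came without male del/del 5, where the females alone give the effect. The highest p of silencing, stress response, cholesterol and X-linked lists came without female fl/fl 2. The log2 fold change of Cnp ranged from -0.178 to 0.0722 and Olig1 from -0.225 to 0.180. Where an arm was left with 1 library, it was assumed to vary like the other groups.

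Depth limits genes with few control reads, such as Slitrk4 with 2 reads and Pcdhb4 with 3 reads in female fl/fl 2. Of 50 genes given a 2-fold change in simulated libraries of the same design, 32 were recovered over both sexes and 17 in females. Of 50 given a 1.5-fold change 2 and 0 were recovered, so absence from the calls says little about small changes. The simulated libraries had no line pairs, batch or correlated genes, so these numbers need not hold for the real ones.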

Other observations

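The genes in the next paragraphs were chosen after their values were seen, and the test of neighbouring genes was set out before its result. Over both sexes, Nlrc5, the activator of MHC class I genes, rose 5.16-fold in the del/del libraries (log2 fold change 2.37, SE 0.324, limma adjusted p = 0.00843), Psmb8 of the immunoproteasome 2.77-fold (1.47, SE 0.226), and the peptide transporter gene Tap2 2.10-fold (1.07, SE 0.219). H2-T23, a nonclassical class I gene, rose 2.25-fold (1.17, SE 0.225). Tap1 had 0.78 (adjusted p = 0.0574, and 0.0104 with the line as a block), while H2-K1 (0.05) and B2m (0.00) did not pass. The GTPase genes Irgm2 (1.75, SE 0.233) and Igtp (1.69, SE 0.241), whose rows overlap, and the inflammatory caspase genes Casp1 (1.06, SE 0.203) and Casp12 (1.24, SE 0.217) rose as well.

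The cytokine genes Lif and Clcf1 rose, with log2 fold changes of 0.89 (SE 0.155) and 1.10 (SE 0.215), and the receptor gene Osmr, with 1.89 (SE 0.298). The acute phase genes Serpina3n (2.33, SE 0.242) and C4b (2.14, SE 0.387), markers of reactive astrocytes, rose 5.03-fold and 4.40-fold. Among genes of neurons, Reln, which guides neuronal migration, rose 3.38-fold (1.76, SE 0.208), the synaptic adhesion gene Nrxn3 2.98-fold (1.58, SE 0.199) and the translation factor gene Eef1a2 6.47-fold (2.69, SE 0.364). The imprinted Zdbf2, which was not in the list of imprinted genes, rose 3.14-fold (1.65, SE 0.310).

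Of 20 such genes that passed, including Synpr, Cadps and Dio2, 0 passed without male del/del 5, 5 without female del/del 2, 9 without female del/del 1 and 12 without female fl/fl 3 or male fl/fl 5. Without female del/del 3, male fl/fl 7, female fl/fl 1 or female fl/fl 2, 15, 16, 17 and 19 passed. With quantile normalization 6 passed and with the line as a block 20, and all 20 kept their direction in each of these settings.

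A hypothesis was that genes that rose lie next to each other along the chromosomes, as they may if deletion opened stretches of chromatin. Neighbours were consecutive genes among those with distinct sequence, so other genes can lie between them. Nrxn3 and Dio2, for example, reach from 88722876 to 90738438 on chromosome 12. Among the 124 genes with distinct sequence that rose, 11 pairs of neighbours both rose, against a median of 2 in 10000 permutations of position (one-sided permutation p = 1e-04, the smallest they can give). Since gene families sit in clusters, the deciding test kept pairs with different first letters: 5 such pairs, against a median of 2 and a central 95% of the permutations that reaches 5 (one-sided permutation p = 0.042), were Nrxn3 and Dio2, Ppp4r4 and Serpina3n, Dlk1 and Meg3, Cadps and Synpr, and Slc4a10 and Ifih1. The excess is small and within that central range, and which pairs share regulation was not tested.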
